A study of Mus musculus with 6 samples.

How the data were processed

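Livers of male mice given municipal effluent (treated municipal wastewater discharge) or distilled water for 90 days were profiled on Affymetrix expression arrays. Per the series' design text, the livers of 3 mice were homogenised together for each RNA sample, so the 3 arrays of a group stand for 9 of its 10 mice. The 6 arrays fall into 3 control pools and 3 effluent pools, taken from the treatment labels and the sample titles. Because each array holds separate animals, the spread between arrays is a spread between pools, which is smaller than that between single mice.

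The deposited per-array values are log2 expression of 35399 probe sets, made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA corrects the background, normalises between arrays and summarises the probes of a probe set. The versions and settings of these programs are not given in the sources used here. The log2 scale was checked on the values, which run from 2.54 to 14.3. The authors' deposited table of the same probe sets holds a group mean in log2, a p-value, a linear ratio and a signed fold change of effluent over control, per the file headers. Its means differ from the 3-array means by at most 7.67e-05 for the control. The test behind the authors' p-value is not given in the sources used here. No scan date or hybridisation batch was given in the sources used here, so a batch that follows the groups cannot be told apart from the treatment. The labelling protocol in the labels speaks of 3' arrays, whereas the probe annotation is that of a whole-transcript mouse gene array. The deposited distributions differ between the groups, and whether the 6 arrays were normalised together is not given in the sources used here.

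Gene names came from GEO's annotation of the array platform. Of the 35399 probe sets, 21789 had 1 gene symbol, 1621 had several and 11989 had none. Probe sets with several symbols or none were left out of the gene tests. A gene was represented by its brightest single-symbol probe set by the mean over all 6 arrays, giving 19938 genes, of which 999 had more than 1 probe set. Gene IDs of 19856 genes were found in the RefSeq table of GRCm38.p6, and 0 symbols had to be changed. The build behind the array annotation is not given in the sources used here, so no coordinates are printed.

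Effluent was compared with control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the log2 values, with group as the only term and Benjamini-Hochberg adjustment over all genes. The threshold was an adjusted p of 0.05. Changes are effluent minus control. Values are given as mean ± SD over 3 arrays, and SE is the moderated standard error of the change. For arrays, the number of arrays limits the precision. On simulated data with 50 changed genes per size among 19938 genes, the test recovered 14% of genes changed 1.5-fold, 66% of those changed 2-fold, 96% at 3-fold and 92% at 4-fold, with 6 false calls among 140. Few genes changed there, so the adjusted threshold was stricter than in the data, where 12341 genes passed. These rates do not carry over to the data.

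Before the data were examined, 55 gene lists were fixed from general knowledge of the liver and of pollutant responses, 17 of them for other cell types, liver zones, time of day or handling. They were tested with limma's camera at its preset inter-gene correlation of 0.01, which asks whether a list's genes differ from all other genes, with Benjamini-Hochberg adjustment over the 55 lists. An estimated correlation and fry, which asks whether the genes of a list move on balance one way, were the alternatives. With an estimated correlation, camera also allows for the small number of arrays (6), which makes passing harder at any correlation. On simulated data with no change 0 of the 55 lists was called, and a list lowered by 0.4 log2 was called with 0 others. The simulated genes were drawn independently, so this does not show how the test behaves on correlated lists. In the data the estimated correlations ran from -0.06 (thyroid hormone list) to 0.94 (exocrine pancreas markers). The rule for named genes was also fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members past the threshold with the largest change from each list. Other genes are said to have been chosen after their values were seen.

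Other settings chosen at the same time were quantile normalisation applied again, median centring of each array, filters on dim genes (mean above the median of all genes, or above 6 log2), the mean of all probe sets of a gene, all probe sets tested separately, an intensity trend with a robust prior, array quality weights, a plain two-sample test, a minimum fold of 1.2 (limma's treat), a replicate block, and each array left out in turn. After the data were seen, 1 more was added because the change depended on the expression level. It is a cyclic loess normalisation of the gene values between arrays, and its changes are called level-matched, that is, relative to genes of the same expression level. Families of genes sharing the start of their symbol, with at least 15 members, were also chosen after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.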

Results

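Gene expression was measured in livers of male mice after 90 days of exposure to municipal effluent, with distilled water as the control. Each group had 3 arrays, and each array carried RNA pooled from 3 mice. The comparison asks which liver genes differ between effluent and control. All 6 arrays held 35399 probe sets, with median log2 values of 4.76 to 4.83 in the control pools and 5.02 to 5.05 in the effluent pools. Between genes, the SD of the log2 values was 1.99 to 2.05 on the control arrays and 1.79 to 1.83 on the effluent arrays. Correlations across genes, which are not independent replicates, were 0.983 to 0.986 within the control group, 0.986 to 0.988 within the effluent group and 0.915 to 0.951 between the groups. The leading principal component held 82.9% of the variance and separated the groups.

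In the deposited values, livers of effluent-treated mice had lower signal for genes of cholesterol and fatty acid synthesis, mitochondrial energy metabolism, the proteasome, MAPK signalling, the circadian clock, sinusoidal endothelium and stellate cells, and higher signal for neutrophil and B cell genes. Relative to genes of the same expression level (level-matched), 1 of the 21 list calls, that for stellate cell markers, was kept, and with repeated quantile normalisation 0 were. Among genes above 6 log2 or above the median level, none of the 19 lower lists passed as lower, and the neutrophil and B cell lists kept too few genes to be tested. Most genes called there were lower, 5092 of 5292 above 6 log2 and 6872 of 7949 above the median level. A list that passed there as higher than other genes may therefore only have fallen less. The level-matched medians were 0.01 for the proteasome, -0.02 for the clock, -0.03 for oxidative phosphorylation and -0.09 for endothelium. Of 19938 genes, 12341 passed an adjusted p of 0.05 (limma), 4752 higher and 7589 lower with effluent. Of these, 2431 were at least 1.5-fold higher and 6110 at least 1.5-fold lower. At an unadjusted p of 0.05, 13184 genes passed, where chance gives 997. The groups did not overlap for 13833 genes, or 69.4%, where chance gives 10%. Of the 55 gene lists, 21 passed (camera), 19 lower and 2 higher, and 0 of them passed with an estimated correlation, where the smallest adjusted p was 0.414. Lists with an estimated correlation below the preset 0.01, such as the circadian clock (-0.01), lost their calls as well. Correlation between genes alone therefore does not explain the loss, here or for the single lists below.

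The change followed the expression level. With genes divided into 10 groups of equal size by mean level, the median change was 0.18 to 0.28 in the 5 dimmest groups. It was -0.96 in group 8, -1.02 in group 9 and -0.64 in the brightest group 10. Level-matched, 6644 genes passed, 3508 higher and 3136 lower, so that 52.8% of calls were higher against 38.5% with the deposited values. Level matching centres the change near 0 at each level, with medians of -0.08 to 0.05 in the 10 groups. A near-even split therefore follows from the method and does not bear on whether the excess of falls is real. Of the 6644 genes, 5034 were called in the same direction in both fits and 303 in opposite directions. Centring each array on its median moved the median of all genes by -0.24 and gave 2360 higher and 9423 lower genes, while quantile normalisation moved it by -0.10 and gave 2568 higher and 7159 lower. Level matching was chosen after the data were seen.

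**Figure D1:**
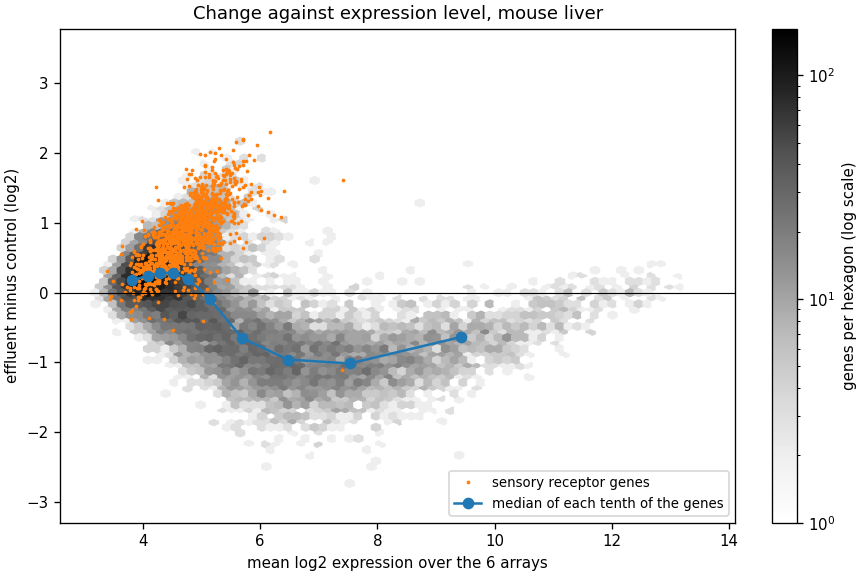
Change in log2 expression (effluent minus control, vertical axis) against mean log2 expression over the 6 arrays (horizontal axis) for 19938 liver genes. Grey hexagons count genes, blue points are medians of 10 equal groups of genes by level, which fall from 0.28 in group 4 to -1.02 in group 9, and orange dots are sensory receptor genes.

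Genes of cholesterol synthesis had the lowest median change among the lists that passed. Of 20 measured members, 18 fell and 0 rose (18 and 0 adjusted over the list alone), with a median change of -1.13 (camera adjusted p = 0.00104, and adjusted p = 0.535 with an estimated correlation). Cyp51, the sterol demethylase, was at 8.05 ± 0.88 in control and 6.01 ± 0.16 in effluent livers (SD, n = 3), a change of -2.04 with an SE of 0.36. Lss, which makes lanosterol, changed by -1.92, and Sqle, squalene epoxidase, by -1.85. Control replicate 1 was highest for these genes, with Cyp51 at 9.07 there and at 7.51 and 7.58 on the other control arrays. Without it the changes were -1.54 for Cyp51, -1.67 for Lss and -1.26 for Sqle, and the mean of the list minus that of other genes was -0.75 instead of -1.07, with all these calls kept. Level-matched, Lss kept its call (-0.96), while Cyp51 (-1.02, adjusted p = 0.0662) and Sqle (-0.97, adjusted p = 0.137) lost theirs. Sqle also lost it in the plain test (adjusted p = 0.0692). The level-matched median of the list was -0.52 (adjusted p = 0.0611), with 4 members lower. In the list of fatty acid and triglyceride synthesis, 22 of 29 genes fell and 3 rose (22 and 3 adjusted over the list alone), with a median of -0.73 (camera adjusted p = 0.014, and adjusted p = 0.414 with an estimated correlation). The fatty acid elongase Elovl6 fell from 8.18 ± 0.19 to 5.81 ± 0.40 (SD, n = 3), or to 0.194 of control, and its level-matched change was -1.35. The synthase Fasn changed by -1.72 and the acyltransferase Dgat1, which makes triglycerides, by -1.56. Level-matched, Dgat1 kept its call (-0.58) and Fasn lost it (-0.69, adjusted p = 0.0678). Level-matched, the median of this list was -0.22 (adjusted p = 0.36).

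In fatty acid oxidation, 19 of 29 genes fell and 0 rose (19 and 0 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 0.00628, and adjusted p = 0.533 with an estimated correlation). The carnitine carrier Slc25a20 changed by -1.37 and the dehydrogenase Acads by -1.30. The level-matched median was -0.07. The list of PPARalpha targets did not pass (adjusted p = 0.0544), although 14 of its 27 genes fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.48 and a level-matched median of -0.13. It passed without control replicate 1 (adjusted p = 0.00288), with median centring (0.0409) and with the replicate block (0.0381), whereas above 6 log2 it passed as higher than other genes (0.0494). Among its genes the thioesterases Acot1 and Acot2 changed by -2.50 and -1.89, and these kept level-matched changes of -1.47 and -0.93. Bile acid synthesis and transport had 17 of 31 genes lower and 1 higher (17 and 1 adjusted over the list alone) and did not pass (adjusted p = 0.0586), but passed without control replicate 2 or effluent replicate 3 (adjusted p = 0.0395 and 0.0442), with median centring (0.0345) and with the replicate block (0.0479), whereas above 6 log2 it passed as higher than other genes (0.0202). Its median was -0.52, and -0.04 when level-matched. Abcg8, part of the sterol exporter of hepatocytes, changed by -1.49. Apoc3, a component of triglyceride-rich lipoproteins, rose from 11.07 ± 0.15 to 11.97 ± 0.03 (SD, n = 3), and level-matched by 1.14.

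Genes of mitochondrial energy metabolism had lower signal. In oxidative phosphorylation, 49 of 69 genes fell and 0 rose (50 and 0 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 1.81e-05, and adjusted p = 0.517 with an estimated correlation). Ndufa2 of complex I changed by -2.04 and Cox4i1 of cytochrome c oxidase by -1.65. In the TCA cycle, 21 of 22 genes fell and 0 rose (21 and 0 adjusted over the list alone), with a median of -0.69 (camera adjusted p = 0.000228, and adjusted p = 0.414 with an estimated correlation). Ogdh and Idh3a, subunits of its dehydrogenases, changed by -1.32 and -1.23, and Idh3a lost its call when level-matched (-0.30, adjusted p = 0.16). Level-matched medians of these lists were -0.03 (adjusted p = 0.531) and -0.15 (adjusted p = 0.506).

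Sugar metabolism and its signals were lower too. For gluconeogenesis, glycolysis and glycogen, 18 of 26 genes fell and 1 rose (18 and 1 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 0.00369, and adjusted p = 0.499 with an estimated correlation). Gys2, the liver glycogen synthase, fell from 11.73 ± 0.12 to 10.33 ± 0.06 (SD, n = 3), with a level-matched change of -1.05. Pdk4, which restrains pyruvate oxidation, changed by -1.90 and the phosphofructokinase Pfkl by -1.84. Pdk4 lost its call when level-matched (-0.91, adjusted p = 0.113) and in the plain test (adjusted p = 0.0619), while Pfkl kept it (-1.08). The change of Pdk4 ran from -2.42 to -1.47 with 1 array left out. In insulin and IGF signalling, 15 of 24 genes fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 0.00342, and adjusted p = 0.414 with an estimated correlation). The kinase Mtor changed by -1.36 and the transcription factor Foxo1 by -1.29, but both calls were lost when level-matched (-0.35 and -0.29, adjusted p = 0.0788 and 0.103). In the glucocorticoid and fasting response, 12 of 21 genes fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.63 (camera adjusted p = 0.026, and adjusted p = 0.499 with an estimated correlation). Level-matched, the medians of these lists were -0.15, -0.20 and -0.10, and none passed (adjusted p = 0.326, 0.325 and 0.516). In amino acid catabolism and the urea cycle, 24 of 48 genes fell and 1 rose (22 and 0 adjusted over the list alone), with a median of -0.31 that was 0.04 when level-matched (camera adjusted p = 0.014, and adjusted p = 0.499 with an estimated correlation). Above 6 log2, where the other genes mostly fell, this list passed as higher than other genes (by 0.39, adjusted p = 0.00162). Bckdha, which acts on branched-chain amino acids, changed by -1.40, and lost its call when level-matched (-0.44, adjusted p = 0.0545).

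**Figure D2:**
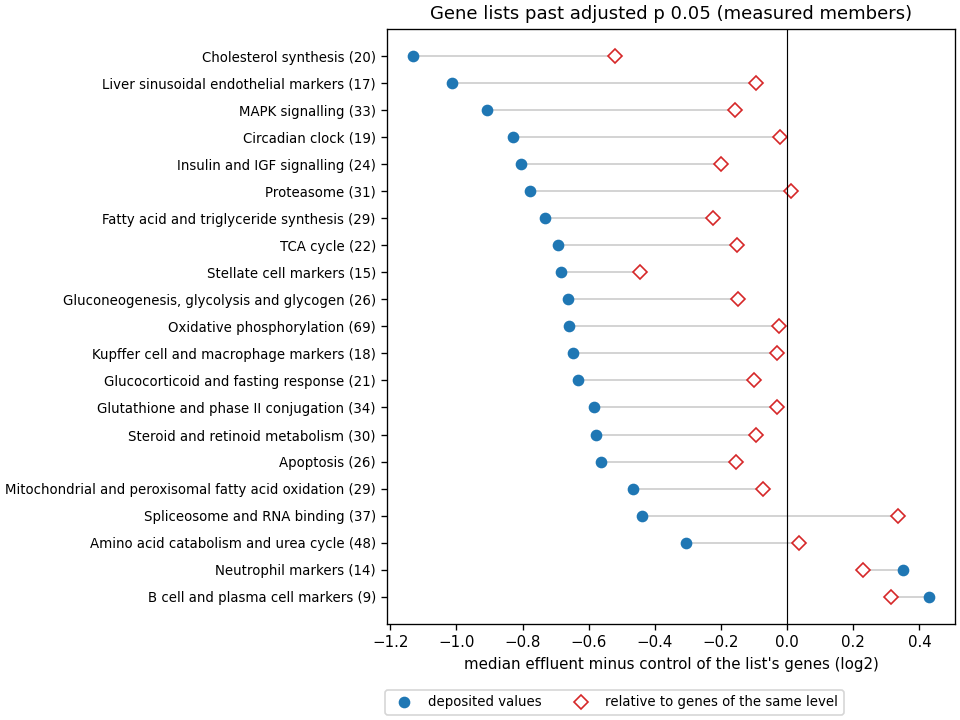
Median change in log2 expression (effluent minus control, horizontal axis) of the 21 gene lists past adjusted p 0.05, with the number of measured genes in parentheses. Blue dots use the deposited values and red diamonds the level-matched values; cholesterol synthesis lies at -1.13 and -0.52, and oxidative phosphorylation at -0.66 and -0.03.

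In glutathione and phase II conjugation, 20 of 34 genes fell and 0 rose (20 and 0 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 0.014, and adjusted p = 0.535 with an estimated correlation). Ugt3a2, a glycosyltransferase, changed by -2.39 and the glutathione transferase Gsta4 by -1.51. The call for Ugt3a2 was lost in the plain test (adjusted p = 0.0715), and its change ran from -3.18 to -1.92 with 1 array left out. Above 6 log2, where the other genes mostly fell, the list passed as higher than other genes (by 0.24, adjusted p = 0.0244). The level-matched median was -0.03. Cytochrome P450 families 1 to 3 (33 genes, 2 higher and 6 lower, or 1 and 5 adjusted over the list alone, adjusted p = 0.538) and the targets of CAR and PXR (20 genes, 2 higher and 5 lower, or 2 and 3 adjusted over the list alone, adjusted p = 0.713) did not pass. In both lists the mean change was below 0 (-0.09 and -0.02) while the median (0.07 and 0.04) was above 0. The medians were 0.18 and 0.20 when level-matched, but -0.17 and -0.20 with median centring. Above 6 log2 both lists passed as higher than other genes (by 0.65 and 0.73, adjusted p = 1.2e-10 and 1.21e-06), and the P450 list also did above the median level (0.44, adjusted p = 0.00922). Cyp2b9, a P450 of both lists, rose from 8.35 ± 0.72 to 9.83 ± 0.27 (SD, n = 3), and level-matched by 2.27 (adjusted p = 0.000803), with its call lost in the plain test (adjusted p = 0.0546) and a range of 1.19 to 1.88 with 1 array left out, whereas Cyp2a22 changed by -2.33. Gadd45b, a stress-induced CAR target, changed by -1.54. Targets of the dioxin receptor AhR (7 genes) had 1 higher and 2 lower (1 and 2 adjusted over the list alone, adjusted p = 0.713). Their median was 0.03, and 0.07 when level-matched, but -0.21 with median centring and -0.12 with quantile normalisation. Among them the AhR repressor Ahrr changed by 0.41 and the quinone reductase Nqo1 by -0.73. The change of Ahrr was 0.17, 0.16 and 0.17 with quantile normalisation, median centring and level matching, and its call was lost in each (adjusted p = 0.247, 0.266 and 0.26) and with a minimum fold of 1.2. Cyp1a1, the best-known AhR target, and the PXR target Cyp3a11 were chosen after their values were seen, and their changes of 0.38 and 0.25 did not pass (adjusted p = 0.0888 and 0.0774). Cyp1a1 passed with the replicate block (adjusted p = 0.0279) and without effluent replicate 1 (0.54, adjusted p = 0.0271), and Cyp3a11 with the intensity trend (adjusted p = 0.0124) and in the plain test (adjusted p = 0.0355).

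Nrf2 targets (18 genes, 1 higher and 8 lower, also adjusted over the list alone) and the metal response (14 genes, 0 higher and 5 lower, also adjusted over the list alone) did not pass either (adjusted p = 0.481 and 0.502). Their medians of -0.21 and -0.38 turned to 0.14 and 0.16 when level-matched. Above 6 log2, where the other genes mostly fell, both lists passed as higher than other genes (adjusted p = 0.00182 and 0.000976). Srxn1, an antioxidant enzyme, changed by -1.16, but by -0.13 when level-matched, where its call was lost (adjusted p = 0.569). The zinc importer Slc39a4 changed by -1.71. The metallothioneins Mt1 and Mt2, chosen after their values were seen, had changes of 0.06 and 0.13 that did not pass (adjusted p = 0.641 and 0.325). Level-matched, Mt1 changed by 0.42 and passed (adjusted p = 0.0175), and with median centring the changes turned to -0.18 and -0.11.

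In steroid and retinoid metabolism, 17 of 30 genes fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -0.58 and a level-matched median of -0.09 (camera adjusted p = 0.0175, and adjusted p = 0.414 with an estimated correlation). Above 6 log2, where the other genes mostly fell, it passed as higher than other genes (by 0.19, adjusted p = 0.0308). Its member Hsd3b5, a male-biased steroid dehydrogenase, was at 9.21 ± 1.56 in control and 7.13 ± 0.51 in effluent livers (SD, n = 3), with overlapping groups. The change of -2.08 was -1.29 without control replicate 1, and its call was lost without effluent replicate 2 or 3 (changes of -1.86 and -2.02), and when level-matched (-1.11, adjusted p = 0.228). Male-biased genes (26 genes, 1 higher and 10 lower, also adjusted over the list alone, adjusted p = 0.25) and female-biased genes (24 genes, 3 higher and 6 lower, also adjusted over the list alone, adjusted p = 0.773) did not pass, with level-matched medians of -0.04 and -0.06, but both passed as higher than other genes above 6 log2 (adjusted p = 0.000277 and 0.00353). Mup21, a urinary protein of the former, changed by -1.59, and the thioesterase Acot3 of the latter by -1.77. Oestrogen receptor targets and egg-protein related genes (17 genes, 2 higher and 8 lower, also adjusted over the list alone) did not pass (adjusted p = 0.346), with medians of -0.62 and, level-matched, -0.06. The oestrogen receptor gene Esr1 changed by -1.01, but by 0.01 when level-matched, where its call was lost (adjusted p = 0.986). In the thyroid hormone list, 10 of 13 genes fell and 1 rose (10 and 1 adjusted over the list alone), which did not pass (adjusted p = 0.077), but passed without control replicate 2 or 3 (adjusted p = 0.0477 and 0.0427) and with the replicate block (0.047). The median was -1.05, and -0.25 when level-matched. Serpina7, the thyroxine-binding globulin, changed by -2.23 and the receptor Thrb by -1.28, the latter with no call when level-matched (-0.25, adjusted p = 0.253).

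Protein turnover and RNA processing genes fell in the deposited values. In the proteasome list, 25 of 31 genes fell and 1 rose (26 and 1 adjusted over the list alone), with a median of -0.78 that was 0.01 when level-matched (camera adjusted p = 0.000141, and adjusted p = 0.414 with an estimated correlation). Psmd7 and Psmd6 of its regulatory particle changed by -1.77 and -1.51. In the spliceosome list, 22 of 37 genes fell and 1 rose (22 and 1 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 0.0141, and adjusted p = 0.56 with an estimated correlation), while the level-matched median was 0.34 in the opposite direction (adjusted p = 0.0143), as was the difference above 6 log2 (0.38, adjusted p = 0.00382). Hnrnpl, a regulator of splicing, changed by -1.26, and its call was lost when level-matched (-0.23, adjusted p = 0.128). Ribosomal protein genes (51 genes, 4 higher and 25 lower, also adjusted over the list alone) did not pass (adjusted p = 0.179), but were higher when level-matched, with a median of 0.33 (adjusted p = 0.000788), and higher than other genes above 6 log2 (adjusted p = 4.41e-08). Rpl26 was an exception with a change of -1.74 and a level-matched change of -1.98. Of the unfolded protein response and ATF4 targets (31 genes, 3 higher and 12 lower, or 3 and 11 adjusted over the list alone, adjusted p = 0.203), the asparagine synthetase Asns changed by -1.63, with no call when level-matched (-0.72, adjusted p = 0.0876). Phgdh, of serine synthesis, changed by 0.98, and its call was lost without effluent replicate 1 or 2 (adjusted p = 0.0635 and 0.0594), and when level-matched (0.74, adjusted p = 0.0782). The median of this list was -0.22, but 0.28 when level-matched, and above 6 log2 it passed as higher than other genes (adjusted p = 0.00402).

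Signalling lists were lower as well. In MAPK signalling, 22 of 33 genes fell and 1 rose (23 and 1 adjusted over the list alone), with a median of -0.91 and a level-matched median of -0.16 (camera adjusted p = 0.000447, and adjusted p = 0.414 with an estimated correlation). The kinases Map2k1 and Mapk14 changed by -2.14 and -1.54. In the apoptosis list, 17 of 26 genes fell and 2 rose (17 and 2 adjusted over the list alone), with a median of -0.56 and a level-matched median of -0.15 (camera adjusted p = 0.014, and adjusted p = 0.414 with an estimated correlation). Diablo, which promotes caspase activity, changed by -2.12 and the initiator caspase Casp8 by -1.50. In the circadian clock, 12 of 19 genes fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.83 and a level-matched median of -0.02 (camera adjusted p = 0.00301, and adjusted p = 0.414 with an estimated correlation). The clock output genes Dbp and Usp2 changed by -2.08 and -1.95, and the repressors Cry2 and Nr1d2 by -1.46 and -1.44. Level-matched, Dbp (-1.07, adjusted p = 0.0821) and Nr1d2 (-0.48, adjusted p = 0.0776) lost their calls.

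Markers of the cells other than hepatocytes moved in both directions. Sinusoidal endothelial markers fell in 14 of 17 genes and rose in 0 (14 and 0 adjusted over the list alone), with a median of -1.01 and a level-matched median of -0.09 (camera adjusted p = 0.00104, and adjusted p = 0.414 with an estimated correlation). The receptors Kdr and Flt4 changed by -1.46 and -1.44. Stellate cell markers fell in 10 of 15 genes and rose in 0 (10 and 0 adjusted over the list alone), with a median of -0.68 (camera adjusted p = 0.0175, and adjusted p = 0.437 with an estimated correlation). Theirs was the 1 call that also passed in the same direction when level-matched, with a median of -0.44 (adjusted p = 0.0214). The list's mean minus that of other genes was -0.56 in the main fit. Its call was lost with quantile normalisation (-0.47, adjusted p = 0.071), above the median level (-0.46, adjusted p = 0.297) and above 6 log2 (-0.23, adjusted p = 0.6). Reln changed by -1.50 and Lrat, which stores retinol, by -1.30. Kupffer cell and macrophage markers fell in 12 of 18 genes and rose in 0 (12 and 0 adjusted over the list alone), with a median of -0.65 and a level-matched median of -0.03 (camera adjusted p = 0.014, and adjusted p = 0.414 with an estimated correlation). The lysozyme gene Lyz2 fell from 8.89 ± 0.25 to 6.64 ± 0.40 (SD, n = 3), and level-matched by -1.23, while the Kupffer lectin Clec4f changed by -1.38 and lost its call when level-matched (-0.39, adjusted p = 0.114).

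Neutrophil markers rose in 8 of 14 genes and fell in 0 (8 and 0 adjusted over the list alone), with a median of 0.35 and a level-matched median of 0.23 (camera adjusted p = 0.00994, and adjusted p = 0.414 with an estimated correlation). Ngp, a granule protein, rose from 4.11 ± 0.28 to 6.05 ± 0.61 (SD, n = 3), or 3.82-fold. The granule protein Ltf changed by 0.81 and the calgranulins S100a9 and S100a8 by 0.69 and 0.58. S100a8 lost its call when level-matched (0.34, adjusted p = 0.0563) and with quantile normalisation (0.30, adjusted p = 0.0685). B cell markers rose in 4 of 9 genes and fell in 0 (3 and 0 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 0.0385, and adjusted p = 0.414 with an estimated correlation). The level-matched median was 0.31 (adjusted p = 0.235). Cr2 and Ms4a1 changed by 0.93 and 0.59. The B cell list's mean minus that of other genes was 0.56 in the main fit. Its call was lost without control replicate 1 (0.50, adjusted p = 0.0593) or effluent replicate 1 (0.49, adjusted p = 0.0582). It was also lost with the mean of all probe sets of a gene (0.53, adjusted p = 0.054) and with quantile normalisation (0.43, adjusted p = 0.0774). The chemokines Ccl5 and Cxcl1 rose by 1.26 and 1.01, and level-matched by 2.14 and 1.06. The inflammatory cytokine list that holds both had 8 higher and 6 lower of 28 genes and did not pass (camera adjusted p = 0.23). In the interferon response, 10 of 34 genes fell and 0 rose (7 and 0 adjusted over the list alone), which did not pass (adjusted p = 0.159). Without control replicate 2 or 3 it passed (adjusted p = 0.0408 and 0.0234), and without control replicate 1 the adjusted p was 0.76. The list's mean minus that of other genes was then 0.0005, against -0.52 with all arrays. With all arrays the median was -0.67, and -0.23 when level-matched. Irf7, its regulator, was at 9.38, 6.42 and 6.15 on the control arrays, and its change of -2.06 was -1.03 without control replicate 1. Its call was lost without any single effluent array (changes of -1.92 to -2.15), and when level-matched (-1.20, adjusted p = 0.232). Hepatocyte markers (16 genes, 3 higher and 2 lower, also adjusted over the list alone) did not pass (adjusted p = 0.192). Their median was 0.14, and 0.08 when level-matched, but -0.10 with median centring. They passed as higher than other genes above the median level (by 0.66, adjusted p = 0.000612) and above 6 log2 (by 0.89, adjusted p = 5.01e-13). The other genes mostly fell there, and level-matched the list did not pass (camera adjusted p = 0.695). In control and effluent livers, albumin, Alb, was at 13.39 ± 0.02 and 13.77 ± 0.02 (SD, n = 3) and the gluconeogenic Pck1 at 11.81 ± 0.04 and 11.38 ± 0.03. Both lost their calls when level-matched (0.08 and -0.22, adjusted p = 0.619 and 0.137).

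**Figure D3:**
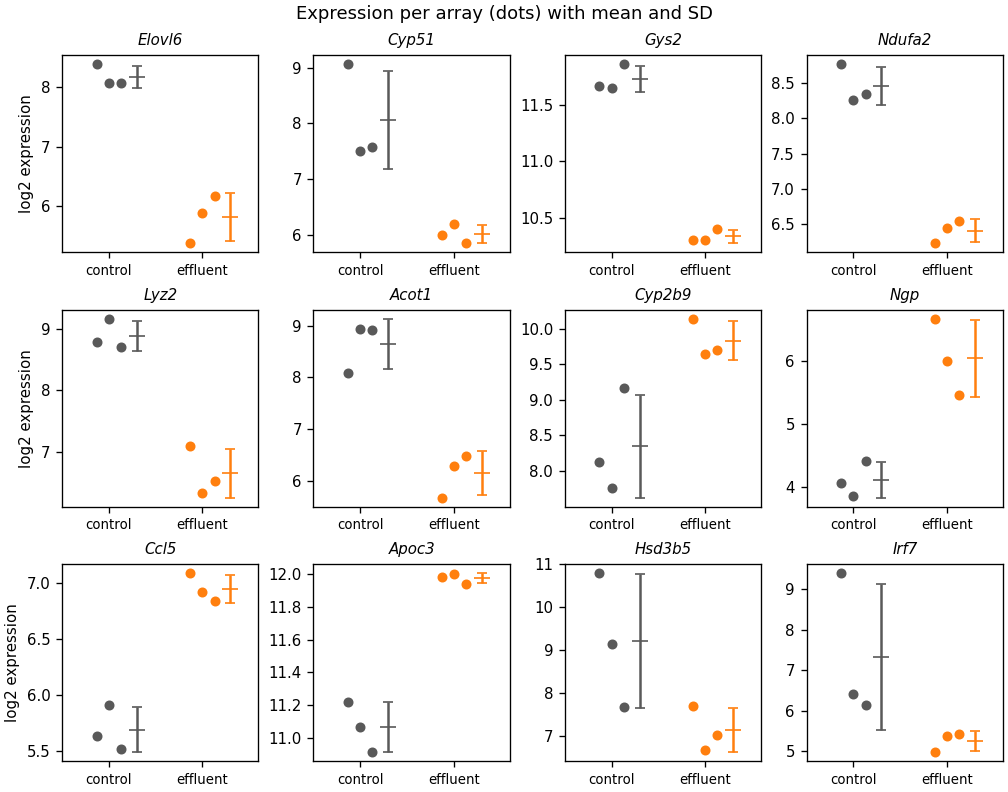
Log2 expression of 12 genes on each of the 3 control and 3 effluent arrays (dots), with the group mean and SD beside them. Vertical axes do not start at 0. Elovl6 lies at 8.18 and 5.81 and Ngp at 4.11 and 6.05 in control and effluent, while Hsd3b5 and Irf7 spread widely among the control arrays.

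The largest falls among genes with non-overlapping groups were those of Uprt (probe set 10601328) and Ubl5. Uprt, related to uracil phosphoribosyltransferases, fell from 7.95 ± 0.32 to 4.97 ± 0.34 (SD, n = 3), a change of -2.98 with an SE of 0.21 (limma adjusted p = 4.13e-05). Ubl5, a ubiquitin-like protein, changed by -2.86. Next were AI506816 (-2.84), Ly96 (-2.79), the partner of the endotoxin receptor, Gm5617 (-2.76), Bpnt2 (-2.75), the deubiquitinase Usp1 (-2.71), Tmem53 (-2.69), Nat8f1 (-2.56), Nat8f5 (-2.52), the replication factor Rfc4 (-2.51) and Acot1 (-2.50). All 12 stayed past the threshold when level-matched, with changes of -2.44 to -1.47.

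The largest rises were mostly of genes with low or moderate signal in control livers. Srsy (probe set 10608426) rose from 6.32 ± 0.67 to 9.77 ± 0.08 (SD, n = 3), a change of 3.46 with an SE of 0.28 (limma adjusted p = 5.79e-05). The microRNA genes Mir680-1, Mir680-2 and Mir505 changed by 3.36, 2.97 and 2.71. The interferon genes Ifna14 and Ifnz changed by 2.81 and 2.54. Others were A530040E14Rik (2.96), Zfp42 (2.71), a pluripotency marker, Gm7982 (2.71), 1700054O19Rik (2.60), Zfp640 (2.43) and Gm10825 (2.41). All 12 stayed past the threshold when level-matched, with changes of 2.49 to 4.44. Several are members of multi-copy families, whose probes can bind near-identical copies, so their values are uncertain.

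The authors' deposited table gave a p-value under 0.05 for 22803 of its 35399 probe sets, with 3108 of them at a ratio of at least 2 and 3905 at least 2-fold lower. Its smallest p-value was 3.78e-20. On the same probe sets and arrays the smallest limma p was 4.55e-09.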

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

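The tests in this part were all chosen after the results they bear on were seen. Bootstrap intervals resampled probe sets or genes, not arrays, so they do not cover the spread between pools. Probe sets outside the gene comparison also differed between the groups. The 1621 probe sets with several gene symbols had a median change of 0.41, with 824 higher and 269 lower (limma on all probe sets). Of the 11989 probe sets with no symbol, 4622 rose and 1631 fell, with a median change of 0.25. These signals lie in data that the comparison of genes does not use, above the level in the control arrays.

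Sensory receptor genes (olfactory, vomeronasal and bitter taste receptors), most of which liver is not known to use, rose on the effluent arrays. Among 1240 receptor probe sets with 1 symbol, 1055 rose and 3 fell, with a median change of 0.83 (95% bootstrap interval 0.79 to 0.86). The median of the receptor genes stayed above 0 under repeated quantile normalisation (0.61) and level matching (0.69). Median centring, which moved every gene by -0.24, gave 0.59 and could not turn it. A compressed log2 range on the effluent arrays is argued against as the whole cause, because the single-symbol receptor probe sets rose by 0.64 (0.59 to 0.67) more than other probe sets of the same control level. Genomic DNA in the effluent targets is a candidate explanation, since the rise was larger by 1.27 (1.14 to 1.63) for probe sets naming 5 or more genes, but RNA that binds many related probes would do likewise. Those probe sets were also brighter in control, with a median of 5.20 against 4.29 for 1 symbol. The 1.27 was not matched on control level, so number of genes and brightness cannot be told apart. A processing batch cannot be told apart from the exposure, since no dates were given. Array medians of the single-symbol receptor probe sets were 4.30, 4.46 and 4.13 in control and 5.13, 5.15 and 5.17 in effluent. That the lowest effluent array lay 0.66 above the highest control array restates the rise and bears on neither explanation. An effect of the effluent itself stays open and untested.

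Oxidative phosphorylation, proteasome and TCA cycle genes fell by a median of -0.72 over 118 genes. A fall shared by all genes of the same level may account for it: level-matched, the median was -0.037 (95% bootstrap interval -0.152 to 0.016), and none of these lists passed. Why genes of middle and high level fell together was not tested. Exposure, batch and a compressed log2 range on the effluent arrays stay open as reasons. The SD between genes was 1.79 to 1.83 on the effluent arrays and 1.99 to 2.05 on the control arrays.

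Neutrophil genes rose by a median of 0.35 over 14 genes. A rise shared by all dim genes could account for part of it, as the level-matched median was 0.23 (95% bootstrap interval -0.03 to 0.36), an interval that holds both 0 and the value before. These explanations cannot be told apart with so few genes. Neutrophil and B cell markers had median control levels of 4.13 and 4.15, and single-symbol receptor probe sets one of 4.29. The receptor genes rose more than either list, by a median of 0.83, and by 0.69 when level-matched. For Ngp, 4 of 2016 genes within 0.1 log2 of its control level rose at least as much, itself included, and whether more neutrophils entered the exposed livers was not tested.

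The count of 12341 genes was obtained by 1 of the 10 splits of the 6 arrays into groups of 3, the real one, and the highest of the other splits gave 0 genes. With 10 splits a share under 0.05 cannot be reached.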

How the results depend on the processing

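The alternatives were planned, except level matching (cyclic loess), which was chosen after seeing the data. Genes past the adjusted threshold (12341) became 7949 among genes above the median level and 5292 above 6 log2, where fewer genes are tested, 8086 with a minimum fold of 1.2, and 6644 when level-matched. At the unadjusted p the filters left 8084 and 5337. With 1.5-fold, 4546 passed above 6 log2 and 3899 when level-matched. Leaving out 1 array gave 10747 to 11830, 11969 to 12782 and 7861 to 9025 genes, and 20 to 24 lists, 5 to 6 of them cell type and handling lists. The replicate block gave 12048 genes, against 12341, and 24 lists, against 21. Deviations of same-numbered arrays correlated at -0.016, 0.013 and 0.064 across genes, and only control 3 correlated best with its own number. These values gave no sign that the numbers pair the arrays, but 3 arrays per group cannot exclude it.

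The 21 lists, 6 of them cell type and handling lists, became 0 and 0 with quantile normalisation and with an estimated correlation, 3 and 1 when level-matched, 3 (all higher) and 1 among genes above the median level, 21 (all higher) and 3 above 6 log2, and 42 and 12 with fry.

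Differences between the mean of a list and that of other genes changed sign above 6 log2, where the genes compared with mostly fell, for 29 of 44 lists, 25 of them called in either fit: oxidative phosphorylation 0.15, proteasome 0.053, TCA cycle 0.059, insulin 0.087, gluconeogenesis 0.11, fatty acid oxidation 0.31, amino acids 0.39, phase II 0.24, Kupffer 0.017, spliceosome 0.38, steroid 0.19, glucocorticoid 0.20, metal 0.47, Nrf2 0.51, PPARalpha 0.036, bile acid 0.32, ribosomal 0.57, male-biased 0.44, female-biased 0.48, periportal 0.56, lipoproteins 0.64, antigen presentation 0.50, complement 0.47, pericentral 0.34 and unfolded protein response 0.45. Above the median level 19 of 47 lists changed sign, of which 4 were called in either fit, fatty acid oxidation (0.074), amino acids (0.15), phase II (0.0013) and the spliceosome (0.11). Level-matched, 16 of 55 did, of which 3 were called in either fit, amino acids (0.0097), the spliceosome (0.34) and ribosomal proteins (0.29), and Esr1 changed by 0.0058. Repeated quantile normalisation changed the sign for 11 lists, of which 1 was called in either fit, the spliceosome (0.093). Median centring changed it for 0 lists, as it must, since it shifts all genes of an array alike. Except for the filters, the cause of these changes was not tested.

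Of 97 named genes, 68 kept direction and side of the threshold under every alternative run. Level matching took 22 calls away with the direction kept, and also that of Esr1, whose direction turned (0.0058, adjusted p = 0.986). The plain two-sample test took 7 (Sqle, Pdk4, Ugt3a2, Hsd3b5, Cyp2b9, Irf7 and Phgdh) and quantile normalisation 4 (S100a8, Hsd3b5, Ahrr and Phgdh). Median centring took those of Ahrr, Alb and Phgdh, a minimum fold of 1.2 those of Ahrr, Alb and Pck1, and the intensity trend those of Hsd3b5 and Irf7. Not run were the other deposited table, which holds group means, a pseudocount, since values are log2, and leaving out probe sets by ID ending, since none has one.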

Other observations

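The families and the correlations between arrays in this part were chosen after the data were seen. Families are genes sharing the start of their symbol. Of 145 families, 25 passed higher and 28 lower (camera), and 0 with an estimated correlation, where the smallest adjusted p was 0.449. Even the olfactory receptors (Olfr), with 913 of 1027 genes higher, went from a camera adjusted p of 8.89e-48 to 0.449. The loss under that setting therefore says little about a family. The sign of the median was kept under every scaling in 20 of the 25 and 26 of the 28. Of these scalings, median centring moved every gene by -0.24, so it could turn only higher families. When level-matched, 10 of the 25 and 6 of the 28 also passed in the same direction. Among these were Krtap, Lce and Defb, higher with medians of 0.69, 0.71 and 0.41, and Mrpl, Vps and Med, lower with medians of -1.13, -0.97 and -0.96 (level-matched -0.19, -0.19 and -0.33). The keratins (Krt) passed higher with a median of 0.17, but -0.07 with median centring, -0.03 with quantile normalisation and -0.01 when level-matched. Ribosomal proteins (Rps and Rpl) did not pass (adjusted p = 0.105 and 0.491), and their medians of -0.36 and -0.18 turned to 0.27 and 0.30 when level-matched.

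The remaining lists did not pass in the comparison of all genes. Of 33 acute phase genes, 5 rose and 7 fell (5 and 6 adjusted over the list alone, adjusted p = 0.346), with the pentraxin Apcs at -1.94. The list passed as higher than other genes above the median level and above 6 log2 (by 0.49 and 0.67, adjusted p = 0.000612 and 7.16e-13), where those genes mostly fell. The extracellular matrix list had 3 higher and 15 lower of 30 (also adjusted over the list alone; adjusted p = 0.192), with the smooth muscle actin Acta2 at -1.36. Pericentral hepatocyte genes had 1 higher and 10 lower of 19, and periportal genes 0 and 4 of 13 (adjusted p = 0.151 and 0.486). Complement and coagulation had 2 higher and 17 lower of 38 (adjusted p = 0.109, and 0.034 with median centring), heat shock 0 and 9 of 18 (adjusted p = 0.159), and lipoproteins 3 and 9 of 27 (adjusted p = 0.743). Immediate-early genes had 0 higher and 10 lower of 25 (adjusted p = 0.244), and antigen presentation 2 and 4 of 15 (adjusted p = 0.773). The p53 response had 3 higher and 10 lower of 20 (adjusted p = 0.326), and the cell cycle 9 and 7 of 37 (adjusted p = 0.326). Inflammatory cytokines had 8 higher and 6 lower of 28 (adjusted p = 0.23). Adjusted over the list alone, the counts since the pericentral list were the same except for lipoproteins (3 and 5), immediate-early genes (0 and 9) and the cell cycle (8 and 7). Above 6 log2, where the other genes mostly fell, several of these lists passed as higher than other genes, namely pericentral (adjusted p = 0.0202), periportal (0.00171), complement (6.1e-05), lipoproteins (2.95e-08) and antigen presentation (0.000259). Medians turned sign when level-matched for complement (-0.30 to 0.06), heat shock (-0.53 to 0.21), lipoproteins (-0.30 to 0.20), antigen presentation (-0.28 to 0.46), periportal genes (-0.18 to 0.20) and the cell cycle (0.06 to -0.10). They did not for acute phase (0.06 and 0.23), matrix (-0.51 and -0.06), pericentral (-0.51 and -0.06), immediate-early (-0.28 and -0.29), p53 (-0.40 and -0.04) and cytokine genes (0.09 and 0.09), although median centring turned the acute phase and cytokine lists to -0.18 and -0.15.

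The remaining marker lists, of neighbouring tissues and of cells not described above, did not pass. Exocrine pancreas markers had 0 of 14 genes past the threshold (camera adjusted p = 0.713), with an inter-gene correlation estimated at 0.94. Their mean minus that of other genes was -0.27, and turned to 0.42 without control replicate 2 (adjusted p = 0.0981). The median was -0.31, and -0.39 when level-matched. Skeletal muscle, intestine and gallbladder, T and NK cell, adipose, erythroid and cholangiocyte markers had adjusted p of 0.203, 0.151, 0.108, 0.346, 0.555 and 0.809. Their medians were 0.09, 0.17, 0.10, 0.29, 0.17 and 0.11, and -0.14, 0.27, -0.08, 0.27, 0.06 and -0.08 when level-matched. Median centring moved the change of every gene by -0.24, and so turned all of these but the adipose list below 0. That follows from the size of their medians. The median, the mean and the test differed in sign for 8 lists, among them the cell cycle, acute phase, AhR target, adipose, erythroid and cholangiocyte lists.

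Differences between control arrays were set against the change. The order of subtraction is arbitrary, so a positive sign tells only that the first-named control array lay nearer to effluent. Across genes, which are not independent replicates, control 2 minus control 3 correlated at 0.45 with effluent minus control 1. The pair control 1 minus control 3 correlated at 0.24 with effluent minus control 2, and control 1 minus control 2 at -0.21 with effluent minus control 3. On the leading principal component control 3 lay at -66.8, control 1 at -52.4 and control 2 at -38.8. The effluent arrays lay at 48.5 to 55.3. Control pools thus also differed along the direction that separated the groups, and the cause was not tested.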
